A study of Arabidopsis thaliana x Arabidopsis arenosa and Arabidopsis suecica with 6 samples.

How the data were processed

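Messenger RNA of rosette leaves was sequenced in 6 samples of Arabidopsis allotetraploids, plants that carry chromosome sets of A. thaliana (T) and of A. arenosa (A). Per the labels, the libraries were made from poly(A) RNA of leaves taken before bolting, with an Illumina mRNA-seq kit, and were read on a Genome Analyzer. The samples were the resynthesized allotetraploid in generation F8 (AlloF8), natural A. suecica, and 4 F1 crosses between AlloF8 and a parental species. The crosses TTTA and TATT hold 3 T genomes and 1 A genome (class T3A1), and the crosses AATA and TAAA hold 1 T genome and 3 A genomes (class T1A3). The order of the letters gives the order in which the parents are named; the labels do not say which parent was the mother.

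The authors deposited, for each sample, a table of RPKM (reads scaled to transcript length and to the mapped reads of the library) with 1 value for the T homoeolog and 1 for the A homoeolog of each transcript in each replicate. The F1 tables hold 3 replicate columns each, and the tables of AlloF8 and A. suecica hold 2 each, which makes 16 libraries, 12 of them from F1 plants. Nothing states that the replicates are separate plants, so no p-value can be taken to measure the spread between plants. Tests on cross means measure the spread between crosses, and tests on libraries measure the spread between these libraries. The genome build was TAIR 9 per the labels; the aligner, the way in which reads were assigned to a homoeolog and the filters are not given in the sources used here. Of the deposited sums of T and A, 99.992% had at most 6 significant digits, so a total appears to have been divided between the homoeologs. None of the 301035 nonzero totals was under 2, and pairs listed at 0, which made up 4.8% to 13.9% of the transcripts of a library, were treated as missing. The deposited values are normalized, so read depth per library is unknown and no counting interval was computed. Summed RPKM over the transcripts of a library ran from 613044 to 781415.

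The tables listed 22890 transcripts of 17885 genes, 13891 of them in all 6 tables, and 3779 genes had more than 1 transcript. Each gene was represented by its transcript with the highest mean. Symbols and product names came from the TAIR10.1 annotation, in which 98.99% of the gene codes were found; no coordinates were used because the builds differ. Total expression is the sum of both homoeologs, and the homoeolog ratio is T over A. A mean per cross was taken over its replicates where at least 2 had a value, and log2 values were taken after adding 0.5 RPKM. Genes with a mean of at least 1 RPKM over the 4 crosses were tested, for the ratio with this mean in each homoeolog.

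The planned test compared the means of the 2 crosses of each class with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg, threshold 0.05), for each homoeolog, for total expression and for the ratio. Its error is the spread between the crosses of a class, so it includes any effect of cross order. Changes of each homoeolog were also tested against the ratio of genome copies, 1.585 on the log2 scale. Cross order was tested as AlloF8 named first against AlloF8 named second, with dosage class in the model. The plan assumed 1 value per sample. After the replicate columns were seen, a second test was added, called the 12-library test: limma on the 12 F1 libraries, with a mean for each of the 4 crosses and replicate number as a block. The block was used because libraries with the same replicate number deviated together from the means of their crosses. The error of the 12-library test is the spread between libraries within a cross, so it compares these 4 crosses and leaves out the spread between crosses. For A. suecica against AlloF8 no test was planned, and limma on the 2 libraries of each was added after the replicate columns were seen. The positions of AlloF8 values between the F1 classes were not tested.

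Gene lists were tested on the comparison of cross means with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry; p-values were adjusted over the lists of a comparison. Members of a list were counted by the 12-library test for each direction. The written lists were circadian clock, flowering time, starch metabolism, nuclear photosynthesis, chlorophyll synthesis, DNA methylation and small RNA, jasmonate, salicylate and defence, ethylene, glucosinolate pathway, flavonoid and anthocyanin synthesis, heat, cold and drought response, and markers of senescent leaf, flower, root and guard cell lineage. Lists by product name were cytosolic ribosome, proteasome, disease resistance protein, cytochrome P450, heat shock, transcription factor, F-box and histone, with plastid and mitochondrial genes by code. Of 257 written entries, 255 matched the annotation; DVR and UGT75C1 were left out. Lists with fewer than 3 measured genes were not tested.

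Genes named in the text were chosen by rule: among genes past the threshold with a mean of at least 5 RPKM, in which the crosses of one class lay above those of the other, the 10 largest changes in each direction; with fewer than 5 calls, the 5 smallest p-values in each direction, given as not past the threshold. For the comparison with the dosage ratio, the 10 most expressed genes that changed by under 0.25 (log2) were named. For A. suecica against AlloF8, the 10 largest ratios in each direction with a mean of at least 10 RPKM were taken. The same rule was applied to the 12-library test. List members were named as examples, and TOC1, GI, FLC, CCA1, LHY and FRI were given where measured. Samples, tests, gene lists, naming rules and most alternatives were fixed before the data were examined.

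The tests were run on simulated data with the spread of the real libraries. For total expression, the planned test found 2% of genes changed by 1 (log2), 52% of those changed by 2 and 82% of those changed by 3, and called 0 unchanged genes among 12193 simulated. The 12-library test found 58%, 96%, 100% and 100% of genes changed by 0.5, 1, 2 and 3, and called 731 unchanged genes, since the simulated spread between crosses is not part of its error. Against the dosage ratio, the planned test found 66% (T) and 42% (A) of the genes moved by 2. The 12-library test called 423 (T) and 667 (A) genes that were simulated at the ratio. These changes were set on the log2 values, so the simulation leaves out the effect of the added 0.5 RPKM on a proportional change. The alternatives chosen beforehand were pseudocounts of 0.1 and 1, a minimum of 5 RPKM or none, libraries rescaled to 1 median, limma without the trend or with robust eBayes, cross order as a block, a slope on genome copies with AlloF8, no organelle genes in the tests, each cross left out, other summaries of the share, and fry or an estimated correlation for the lists. Alternatives added after the data were seen were the 12-library test with its own settings, other ways to choose a transcript, pairs at 0 taken as 0, values in all 12 libraries, single replicates left out, and the share without organelle genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures. No column of values in the deposited tables was left unused (0 columns).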

Results

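Leaf mRNA was measured in F1 allotetraploids that carried either 3 T genomes and 1 A genome (class T3A1, crosses TTTA and TATT) or 1 T genome and 3 A genomes (class T1A3, crosses AATA and TAAA), with 3 libraries per cross. The resynthesized parent AlloF8 and natural A. suecica, both with equal numbers of T and A genome copies, had 2 libraries each. The data hold, for each gene, an RPKM value of the T homoeolog and of the A homoeolog, so that the output of each genome and their total could be followed as the number of genome copies changed. Read depth is unknown, because the values were deposited in normalized form.

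The first question was how far the share of expression from each genome followed the number of its copies. The T homoeologs made up 72.4% ± 1.5 (SD, n = 3 libraries) of all expression in TTTA and 72.0% ± 2.1 (SD, n = 3) in TATT, but 22.3% ± 1.8 (SD, n = 3) in AATA and 21.7% ± 1.4 (SD, n = 3) in TAAA. In AlloF8 the share was 47.3% ± 3.6 (SD, n = 2) and in A. suecica 45.9% ± 3.2 (SD, n = 2). The median gene had a T share of 75.2% in TTTA and TATT, 23.4% in AATA, 23.2% in TAAA, 49.4% in AlloF8 and 49.8% in A. suecica. The distance between the classes was larger than the spread between libraries and between the crosses of a class. With 2 crosses per class, an exact permutation test cannot reach p < 0.05 here and none was run.

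**Figure D1:**
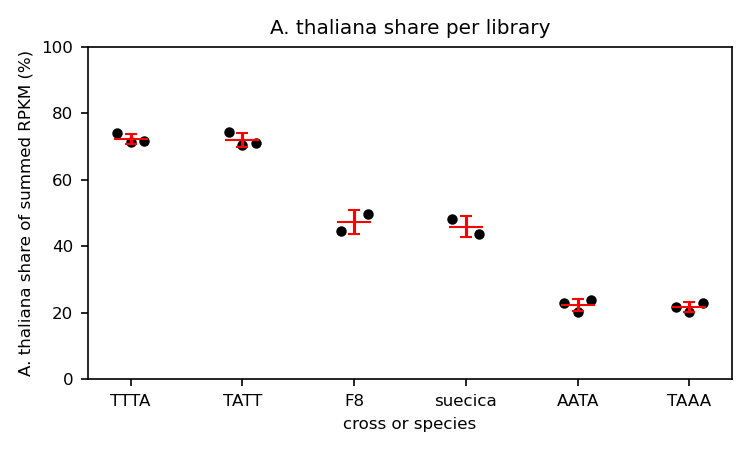
Share of expression from the A. thaliana (T) homoeologs, in percent of summed RPKM, in each of the 16 libraries (points) of the 6 samples, with the mean and standard deviation of each sample. The crosses with 3 T genomes lay near 72%, those with 1 T genome near 22%, and AlloF8 and A. suecica between them.

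The T homoeologs of nearly all genes were higher where 3 T genomes were present. The median T homoeolog was higher by 1.42 on the log2 scale in T3A1 than in T1A3, with 0.90 and 1.99 as the 10th and 90th percentiles over genes. Among the largest rises, SEN1, a gene induced in darkness and senescence, rose from 2.32 ± 1.36 RPKM in T1A3 to 53.5 ± 4.24 RPKM in T3A1 (SD, n = 2 crosses each). PAR1, a repressor of shade responses, rose from 1.13 ± 0.131 to 21.0 ± 4.50 RPKM, and EBP, an ethylene response factor, from 8.95 ± 3.61 to 110 ± 9.57 RPKM (SD, n = 2 crosses each). In total expression the libraries of a cross lay far apart for SEN1 (82.3, 14.4 and 90.5 RPKM in TTTA). PAR1 had no value in replicate 2 of TATT and TAAA. A few T homoeologs went the other way although their genome was present in more copies: the pathogenesis-related gene PRB1 fell from 51.9 ± 11.8 to 0.911 ± 0.128 RPKM and the basic chitinase gene HCHIB from 41.6 ± 6.24 to 5.33 ± 0.801 RPKM (SD, n = 2 crosses each).

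With limma, 12839 of 13457 T homoeologs (95.4%) were higher in T3A1 and 27 (0.201%) were lower. The 10 largest rises were those of AT2G01021 (log2 8.40), AT3G50685 (5.65), SEN1 (4.35), AT2G20670 (3.95), the dormancy and auxin associated gene AT2G33830 (3.95), the gibberellin-regulated gene GASA6 (3.92), AT3G15450 (3.75), PAR1 (3.71), the cold-regulated gene COR15A (3.63) and EBP (3.60). The adjusted p was 0.00363 for COR15A and at most 0.000649 for the other 9. In total expression AT2G01021 had 6.09 to 8.44 RPKM in replicate 1 of the 4 crosses and 2970 to 8530 RPKM in replicates 2 and 3, so its place rests on libraries far apart. The largest falls were those of PRB1 (log2 -5.20, SE 0.209, adjusted p = 0.000636), the myrosinase-binding protein gene MBP2 (-3.01, SE 0.736, adjusted p = 0.0106), HCHIB (-2.85, SE 0.197, adjusted p = 0.000636), AT3G43722 (-2.68), the mitochondrial gene ATMG01390 (-2.52), the auxin conjugate hydrolase gene ILL5 (-2.07), AT1G72290 (-1.78), AT2G43580 (-1.77), AT3G47540 (-1.76) and the defensin gene PDF1.2c (-1.56, SE 0.212, adjusted p = 0.00119). The libraries of a cross also lay far apart in total expression for PRB1 (13, 1480 and 59.6 RPKM in TATT) and MBP2 (760, 32.1 and 549 RPKM in AATA). The 12-library test called 12931 T homoeologs higher and 33 lower, of 13423.

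The T homoeologs of each gene list were set against those of the other genes. Camera called 11 lists for the T homoeologs, 10 lower and 1 higher than the other genes, and 5 lists for the A homoeologs, and none with an estimated correlation. Camera compares t statistics, in which a change is divided by its error, so a list called lower need not have a smaller rise. The lists of heat, cold and drought response and of plastid genes were called lower with medians of 1.81 and 1.93. Of 13 jasmonate genes 9 rose and 4 did not pass, with a median of 0.94, and camera called this list lower (adjusted p = 2.06e-10, and 0.211 with an estimated correlation). The list of salicylate and defence, also called lower, had 7 rises in 13 genes with a median of 1.35 (adjusted p = 9.86e-06, and 0.5 with an estimated correlation), and so was the glucosinolate pathway, with 21 rises and 1 fall in 22 genes and a median of 1.26 (adjusted p = 1.82e-06, and 0.319 with an estimated correlation). In total expression, replicate 2 of the crosses stood apart from the other replicates in several lists, with 13 genes higher and 0 lower for salicylate and defence, 0 and 5 for jasmonate and 0 and 30 for nuclear photosynthesis. Adjusted over the list alone, the counts of rises were 9 for jasmonate, 7 for salicylate and defence and 21 for glucosinolates. The list called higher was the proteasome, in which all 42 genes rose, by a median of 1.53 (adjusted p = 0.0126, and 0.5 with an estimated correlation; 0.0213 and 0.495 on the 12 libraries). All 35 measured genes of nuclear photosynthesis rose, by a median of 2.11, and 288 of 296 cytosolic ribosome genes with a 12-library test rose, by a median of 1.88 over the 297 measured. In the planned test camera called neither of these lists (adjusted p = 0.238 and 0.801), and on the 12 libraries it called both higher (adjusted p = 0.0232 and 8.76e-07, and 0.885 and 0.334 with an estimated correlation).

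The A homoeologs mirrored this: most were lower in T3A1, where 1 A genome was present, than in T1A3, with 3. The median change was -1.43 on the log2 scale, with -2.03 and -0.84 as the 10th and 90th percentiles. PR1, a marker of salicylate signalling, fell from 1930 ± 731 to 100 ± 12.1 RPKM, HCHIB from 120 ± 27.5 to 2.68 ± 0.42 RPKM, and MBP2 from 214 ± 192 to 3.34 ± 1.09 RPKM (SD, n = 2 crosses each). In total expression the libraries of a cross lay far apart for PR1 (47.6, 4380 and 183 RPKM in TATT, 578, 4570 and 215 in AATA). Its total did not pass the 12-library test (adjusted p = 0.0938). Against this trend, the A homoeolog of PAR1 rose from 3.68 ± 0.911 to 10.9 ± 4.73 RPKM and that of AZI1, a gene of systemic immunity, from 54.5 ± 25.0 to 125 ± 5.50 RPKM (SD, n = 2 crosses each).

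Of 13476 A homoeologs tested with limma, 12574 (93.3%) were lower and 25 (0.186%) higher in T3A1. The largest falls were those of AT3G47540 (log2 -5.75), MBP2 (-5.47), AT3G16670 (-5.40), HCHIB (-5.23), AT1G24145 (-4.45), PR1 (-4.21), AT5G55050 (-4.18), AT5G18470 (-4.02), AT1G65500 (-3.95) and AT5G42530 (-3.92), with adjusted p from 0.000961 to 0.00128. The largest rises were those of AT2G25964 (2.79), AT1G50290 (2.36), AT1G69252 (1.75), AT5G18840 (1.56), AT1G27580 (1.45), AT1G27540 (1.44), PAR1 (1.40, SE 0.345), AZI1 (1.27, SE 0.347), AT1G67105 (1.01) and AT1G25230 (0.93), with adjusted p from 0.000961 to 0.0397. The 12-library test called 13025 A homoeologs lower and 32 higher, of 13442. All 13 measured A homoeologs of the jasmonate list fell, by a median of -2.05, and all 35 of nuclear photosynthesis fell, by a median of -1.37; camera called neither list against the other genes (adjusted p = 0.790 and 0.937).

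The ratio of T to A within each gene, which does not depend on the scaling of a library except through the added 0.5 RPKM, was higher in T3A1 for nearly every gene, by a median of 2.87 on the log2 scale (2.31 and 3.41 as the 10th and 90th percentiles). Some genes nevertheless kept 1 homoeolog in the majority at both dosages. The T homoeolog made up 94.2% ± 2.20 of ESP mRNA in T1A3 and 96.4% ± 0.291 in T3A1; ESP encodes the epithiospecifier protein, which directs glucosinolate breakdown. In the opposite direction, the T homoeolog gave 1.75% ± 0.346 of the mRNA of the defensin gene LCR67 in T3A1 and 1.70% ± 0.0854 in T1A3, and 10.5% ± 2.47 and 8.48% ± 1.72 of that of PDF1.2, a jasmonate-responsive defensin gene (SD, n = 2 crosses each).

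With limma, 13352 of 13398 genes had a higher ratio in T3A1 and 5 a lower one. The largest rises were those of AT2G01021 (log2 9.32, with libraries as far apart as stated above), AT3G50685 (6.66), AT5G18470 (6.05), the plastid gene ATCG00020 (5.90, SE 2.32), the glucanase gene BG3 (5.89), AT3G16670 (5.76), PR1 (5.66), AT1G04800 (5.54), the plastid gene ATCG00470 (5.54, SE 1.84) and AT1G24145 (5.36). Their adjusted p was at most 5.5e-06, except for ATCG00020 (0.0431) and ATCG00470 (0.0231). Among the 5 falls, PRB1 (-3.35, adjusted p = 0.0266), ATMG01390 (-3.05, adjusted p = 0.0145) and AT3G43722 (-1.45, adjusted p = 0.0484) met the naming rule; the others, named after their values were seen, were AT2G40205 (-1.12, adjusted p = 0.0443) and AT4G29710 (-0.55, adjusted p = 0.0263). None of the 5 passed the 12-library test (adjusted p from 0.0822 to 0.612), which called 13322 of 13365 ratios higher and 2 lower, those of AT1G50290 (-0.41) and AT2G25964 (-0.54). Of the 13398 genes tested for the ratio, 12140 had values in all 12 libraries. Among the 13398, 67 had a T share over 50% in all 6 T1A3 libraries, among them AT2G45180, PCR1, ESP, AT2G41090, TIR and UBQ3. The A share was over 50% in all 6 T3A1 libraries for 214 genes, among them AT1G72290, PRB1, PDF1.2c, the chitinase-like gene AT2G43590, LCR67, PDF1.2, the glutathione transferase gene GSTF3 and VSP1.

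A homoeolog whose expression followed its copy number would differ by 1.585 (log2) between the classes, and the next comparison asked which genes departed from that. The added 0.5 RPKM makes such a difference smaller where expression is low, so falling short of 1.585 need not be a departure there. In a small set, the class means of a homoeolog differed by little. Among T homoeologs, the metallothionein gene MT1C had 29.2 ± 0.43 RPKM in T3A1 and 34.3 ± 2.94 in T1A3, and the defence regulator gene ACD6 had 21.2 ± 0.136 and 18.5 ± 1.11 RPKM (SD, n = 2 crosses each). Among A homoeologs, the beta-galactosidase gene BGAL1 had 148 ± 7.58 RPKM in T3A1 and 142 ± 7.23 in T1A3, and RABG3B, a small GTPase gene of vesicle transport, had 12.7 ± 0.744 and 11.4 ± 1.92 RPKM (SD, n = 2 crosses each).

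For the T homoeologs, limma called 219 of 13457 genes away from the dosage ratio, 32 beyond it and 187 short of it, and 48 of the 219 had changed by under 0.25. Those with the highest expression were AT5G35525 (log2 -0.21), MT1C (-0.23), the histone gene AT5G10390 (0.02), ACD6 (0.20), the ribosomal protein gene RPL10B (0.03), AT3G04230 (0.11), the acetyltransferase gene NATA1 (-0.15), CP1 (0.00), NUDT5 (-0.16) and OMTF3 (-0.06), with adjusted p from 0.0364 to 0.0498. The libraries of a cross lay far apart in total expression for AT5G35525 (17, 490 and 19.3 RPKM in TATT). For the A homoeologs 82 of 13476 genes differed from the ratio, 25 beyond it and 57 short of it, and 23 had changed by under 0.25: BGAL1 (0.06), MEE14 (0.06), the kinase gene STY46 (-0.01), AT4G13500 (-0.05), RABG3B (0.16), PRE1 (0.15), OFP15 (0.01), AT3G18535 (-0.12), the RNA exosome gene RRP41 (-0.05) and AT3G01490 (0.04) had the highest expression, all with adjusted p = 0.0494. A further 12724 T and 12553 A homoeologs differed from 0 and not from the ratio, which does not show that they followed it; for 9206 and 9735 genes the 95% interval excluded 0 and held the ratio. These counts rest on the settings: with pseudocount 1 they were 3998 (T) and 1527 (A), with a minimum of 5 RPKM 6 and 9, and in the 12-library test 4586 and 4901. The median T change was 1.56 among genes of at least 5 RPKM and 1.77 among those of at least 20 RPKM, and the median A change was -1.44 and -1.39.

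**Figure D2:**
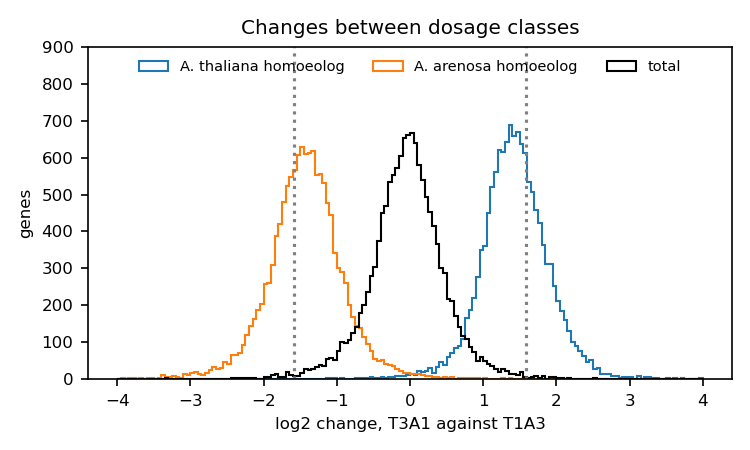
Histograms of the log2 change between T3A1 and T1A3 over genes for the T homoeolog, the A homoeolog and their total, with dotted lines at the ratio of genome copies on the log2 scale. The x axis gives the difference between the class means of the log2 values of the crosses, and the y axis the number of genes. Values beyond 4 in either direction are not drawn. The medians were 1.42, -1.43 and -0.03.

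Total expression, the sum of both homoeologs, asks whether a gene's overall output changed when one genome replaced the other. The medians of the classes were close (-0.03 on the log2 scale, -0.64 and 0.55 as the 10th and 90th percentiles), while single genes differed widely. In the 12-library test HCHIB fell from 162 ± 21.3 RPKM in T1A3 to 8.01 ± 1.22 in T3A1, PAD3, the last enzyme of camalexin synthesis, from 277 ± 244 to 51.9 ± 35.2, and the abscisic acid-responsive gene LTI65 from 27.4 ± 0.0926 to 4.12 ± 0.508 RPKM (SD, n = 2 crosses each). These SDs are between cross means, and the libraries of a cross could lie further apart. In AATA, LTI65 had 36.6, 7.88 and 37.6 RPKM and HCHIB 270, 50 and 211. In TATT, PAD3 had 148 and 5.61 RPKM in replicates 2 and 3. HCHIB and PAD3 had no value in TATT replicate 1, and LTI65 none in replicate 2 of TTTA and TATT. In the other direction, the dormancy-associated gene DYL1 rose from 21.5 ± 1.47 to 101 ± 6.97 RPKM, EBP from 21.8 ± 6.83 to 125 ± 11.1, SEN1 from 10.1 ± 6.75 to 65.2 ± 3.98 and PAR1 from 4.81 ± 1.04 to 31.9 ± 9.23 RPKM (SD, n = 2 crosses each).

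With 2 crosses against 2, limma called 0 of 13535 genes for total expression (3455 at unadjusted p under 0.05, smallest adjusted p = 0.0546), and the list tests with fry also called 0 of the lists. The genes with the smallest p, all with adjusted p = 0.0546 and so not past the threshold, were AT4G13495 (log2 2.18), AT1G50290 (2.32), DYL1 (2.21), AT3G05160 (1.78) and AT3G06125 (1.99), and HCHIB (-4.26), LTI65 (-2.60), the phloem protein gene PP2-A2 (-2.17), the kinase gene AT5G39000 (-2.00) and AT1G75290 (-2.00). The 12-library test, which compares these 4 crosses and leaves out the spread between crosses, called 5181 of 13500 genes (38.4%), 2286 higher and 2895 lower in T3A1. After each library was rescaled to 1 median the balance was the other way, with 2965 higher and 2272 lower. The largest rises were those of AT2G33830 (log2 3.07, SE 0.184, adjusted p = 3.67e-05), AT2G25964 (2.74), PAR1 (2.55, SE 0.147, adjusted p = 8.29e-05), AT2G20670 (2.53), EBP (2.50, SE 0.176, adjusted p = 5.62e-05), SEN1 (2.50, SE 0.469, adjusted p = 0.00371), AT1G50290 (2.33), AT4G13495 (2.24), DYL1 (2.23, SE 0.276, adjusted p = 0.000566) and AT1G30280 (2.20). The largest falls were those of AT3G47540 (-4.33), MBP2 (-3.98), HCHIB (-3.92, SE 0.652, adjusted p = 0.00286), ILL5 (-3.78), BG3 (-3.08), AT1G24145 (-3.07), AT1G72290 (-2.97), LTI65 (-2.95, SE 0.326, adjusted p = 0.000798), PRB1 (-2.91) and PAD3 (-2.86, SE 0.402, adjusted p = 0.0014). The count was 2907 without the replicate block, 1448 and 1526 without replicate 1 and replicate 3 of each cross, 3198 without TTTA and 2101 without TAAA. The planned test called 2, 67, 3891 and 1385 genes without TTTA, TATT, AATA and TAAA.

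**Figure D3:**
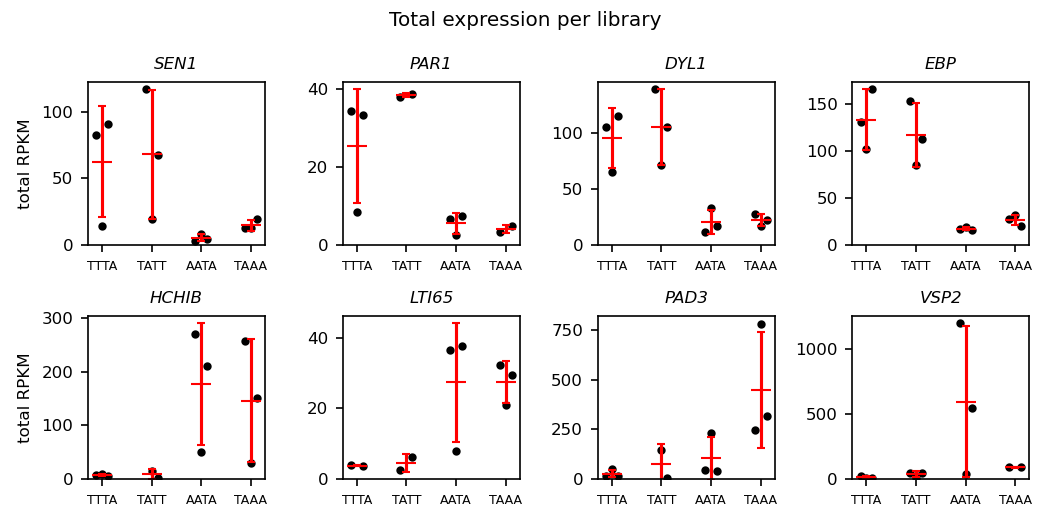
Total expression (RPKM, y axis) of SEN1, PAR1, DYL1, EBP, HCHIB, LTI65, PAD3 and VSP2 in the libraries of the 4 F1 crosses (x axis); points are libraries and red bars give the mean and standard deviation of each cross, drawn down to 0. HCHIB had 162 RPKM in T1A3 and 8.01 RPKM in T3A1, and DYL1 had 21.5 and 101 RPKM (class means).

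Among the gene lists, camera called those of the cytosolic ribosome and of nuclear photosynthesis higher in T3A1 in total expression. The rises, falls and p-values of single genes are from the 12-library test, which leaves out the spread between crosses. In the planned test 0 genes of either list passed, and 0 when adjusted over the list alone. Of 297 measured cytosolic ribosome genes, 121 rose, 17 fell, 158 did not pass and 1 had no 12-library test (132 and 18 adjusted over the list alone; camera adjusted p = 5.93e-06, and 0.927 with an estimated correlation; 7.38e-11 and 0.882 on the 12 libraries). Of 35 genes of nuclear photosynthesis, 9 rose and 26 did not pass (8 rises adjusted over the list alone; camera adjusted p = 0.00128, and 0.927 with an estimated correlation; 0.000346 and 0.882 on the 12 libraries). The 9 included RBCS3B, a small subunit gene of Rubisco (log2 0.94, SE 0.156, adjusted p = 0.00216), the plastocyanin gene PETE2 (0.81, adjusted p = 0.00433) and the light-harvesting gene LHCA4 (0.59, adjusted p = 0.0122). In RPKM, RBCS3B had 1490 in T3A1 and 798 in T1A3, PETE2 2740 and 1600, and LHCA4 3750 and 2480. Replicate 2 of the crosses stood apart from the other replicates in this list, with 30 of the 35 genes lower and 0 higher.

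Camera called the lists of DNA methylation and small RNA and of jasmonate lower in T3A1. Single genes were again read in the 12-library test. The planned test called 0 genes of either list, and 6 and 0 genes when adjusted over the list alone. Of 18 measured genes of DNA methylation and small RNA, 10 fell, 2 rose and 6 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 0.00767, and 0.927 with an estimated correlation; 0.0201 and 0.882 on the 12 libraries). The falls included the DNA demethylase genes DML2 (-1.18, SE 0.139, adjusted p = 0.000666), DME (-0.95) and ROS1 (-0.48), the small RNA effector gene AGO1 (-0.76, adjusted p = 0.00144), DCL4 (-0.69), the methyltransferase gene CMT3 (-0.64) and NRPE1 (-0.63), and the rises were those of DRM2 (0.28, adjusted p = 0.0355) and SUVH2 (0.35, adjusted p = 0.034). Of 13 jasmonate genes, 5 fell and 8 did not pass (6 falls adjusted over the list alone; camera adjusted p = 0.00641, and 0.927 with an estimated correlation). On the 12 libraries camera did not call the jasmonate list (adjusted p = 0.137, and 0.882 with an estimated correlation), and in replicate 2 of the crosses 5 genes of this list were lower than in the other replicates and 0 higher, VSP1 by -3.02 and VSP2 by -2.78. The falls were those of LOX2, a lipoxygenase of jasmonate synthesis (-0.94, SE 0.204, adjusted p = 0.00736), VSP1 (-2.32, adjusted p = 0.00546), VSP2 (-2.82, adjusted p = 0.00125), PDF1.2 (-1.01, adjusted p = 0.0371) and JAR1 (-0.72, adjusted p = 0.0414). LOX2 had 660 RPKM in T3A1 and 1360 in T1A3. VSP1 and VSP2 also differed between the T1A3 crosses, with 2070 and 596 RPKM in AATA and 233 and 90 RPKM in TAAA, against 46.6 and 11.3 in TTTA and 148 and 35.4 in TATT; VSP2 was listed at 0 in TAAA replicate 2, which its mean leaves out.

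The other lists were not called by camera with the preset correlation in the planned test. The rises, falls and p-values of their single genes are from the 12-library test. For salicylate and defence 1 of 13 measured genes rose, 5 fell and 7 did not pass (1 and 5 adjusted over the list alone; adjusted p = 0.791), with falls of ICS1, which makes salicylate precursor (-1.41), PAD3 (-2.86), EDS5 (-1.75), EDS1 (-1.04) and NPR1 (-0.45) and a rise of SAG101 (0.70); in replicate 2 of the crosses 13 genes of this list were higher than in the other replicates and 0 lower. The glucosinolate pathway had 2 rises and 7 falls in 22 genes (2 and 8 adjusted over the list alone; adjusted p = 0.686), among them ESP (1.42, adjusted p = 0.000421), the myrosinase gene TGG2 (-1.89, adjusted p = 0.000204), CYP79B2 (-1.82), CYP79F2 (-1.33) and ESM1 (-0.86). Heat shock genes had 5 rises and 19 falls in 65 genes (5 and 19 adjusted over the list alone; adjusted p = 0.0763 in the planned camera test and 0.0166 in that on 12 libraries, 0.882 with an estimated correlation); in replicate 2 of the crosses 22 genes of this list were higher than in the other replicates and 3 lower (camera adjusted p = 0.00456, and 0.614 with an estimated correlation). The ethylene list had 3 falls in 12 genes (3 adjusted over the list alone; adjusted p = 0.490), of ACO4 (-0.97), EIN3 (-0.50) and ERS1 (-0.44). Flowering time had 3 rises and 6 falls in 17 genes (3 and 7 adjusted over the list alone; adjusted p = 0.686), with rises of the flowering repressor genes MAF2 (1.06, adjusted p = 0.000166; 13.3 and 6.05 RPKM), FLM (0.97) and MAF3 (0.38), and falls of FLK (-0.61, adjusted p = 0.00108), FRL1 (-0.65), LD (-0.52), FY (-0.43), AGL24 (-0.43) and FCA (-0.36). The circadian clock had 3 rises, of ELF4 (0.67), LUX (0.66) and PRR7 (0.39), and 1 fall, of ELF3 (-0.50), in 12 genes (3 and 1 adjusted over the list alone; adjusted p = 0.507).

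For the remaining lists the 12-library test gave counts of rises and of falls. Chlorophyll synthesis had 2 rises and 1 fall in 12 genes (2 and 1 adjusted over the list alone; adjusted p = 0.686), including PORB (0.95) and GUN5 (-0.47). Starch metabolism had 3 and 2 in 16 (3 and 2 adjusted over the list alone; adjusted p = 0.686), including the granule-bound starch synthase gene GBSS1 (-1.37). Flavonoid and anthocyanin synthesis had 0 and 2 in 4 (0 and 3 adjusted over the list alone; adjusted p = 0.449), F3H (-1.38) and FLS1 (-0.74). The heat, cold and drought response had 3 and 2 in 9 (4 and 3 adjusted over the list alone; adjusted p = 0.686), among them COR15A (1.08, adjusted p = 0.0477) and HSP70 (-1.93, adjusted p = 0.000451). By product name, cytochromes P450 had 16 and 28 in 85 (17 and 29 adjusted over the list alone), disease resistance proteins 18 and 20 in 73 (20 and 23), F-box proteins 13 and 23 in 83 (14 and 24), the proteasome 4 and 9 in 42 (4 and 7) and histones 1 and 0 in 13 (0 and 0), each with adjusted p = 0.686. Transcription factors had 27 and 42 in 182 (27 and 42 adjusted over the list alone; adjusted p = 0.898), plastid genes 0 and 1 in 7 (0 and 1; adjusted p = 0.304) and mitochondrial genes 0 and 1 in 3 (0 and 1; adjusted p = 0.686). In replicate 2 of the crosses, 45 disease resistance genes were higher than in the other replicates and 0 lower, 10 chlorophyll synthesis genes were lower and 0 higher, and 2 genes of the heat, cold and drought response were higher and 6 lower (camera adjusted p = 1.31e-09, 4.45e-09 and 0.0275, and 0.582, 0.326 and 0.326 with an estimated correlation). Of the markers of other cells or stages, 3 genes of senescent leaf were measured, SAG13, NAP and SAG21, and 0 passed the test (0 adjusted over the list alone; adjusted p = 0.686); only SHR was measured for root (-0.21, adjusted p = 0.102) and FAMA for the guard cell lineage (-0.26, adjusted p = 0.147). No flower marker was measured.

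A small set of clock and flowering genes was read in every comparison. For the clock gene TOC1, the T homoeolog rose by 1.69 and the A homoeolog fell by 1.18 on the log2 scale, with a total of 54.9 ± 9.56 RPKM in T3A1 and 54.0 ± 3.99 in T1A3 (SD, n = 2 crosses each; adjusted p = 0.966). For GI, a link between clock and flowering, the changes were 2.39 and -1.19, with a total change of 0.22 (adjusted p = 0.491). For FLC, a repressor of flowering, the T homoeolog rose by 1.51 and the A homoeolog fell by 2.47, and the total was 23.8 ± 0.543 and 34.0 ± 15.3 RPKM (SD, n = 2 crosses each; adjusted p = 0.462). CCA1 had values in 4 of the 12 F1 libraries and LHY in 0, and neither was tested. FRI had values in all 6 T1A3 libraries (2.72 RPKM, lowest 2.19, with a T share of 5.19%) and in 0 of the 6 T3A1 libraries, and took no part in the tests. Totals under 2 RPKM are listed as 0, so a T3A1 total lowered only by the fewer A copies could also go unlisted.

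The order of the parents' names separates the crosses within a class and asks whether a cross and its counterpart differ. Between TTTA and TATT no gene passed the test, while TAAA and AATA differed in many genes. In TAAA, the galactinol synthase gene GolS2 had 58.2 RPKM against 6.63 in AATA, and FSD1, an iron superoxide dismutase gene, 44.2 against 10.8. In AATA, VSP1 had 2070 RPKM against 233 in TAAA, and the beta-amylase gene BAM5 182 against 22.8.

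Over both classes limma called 0 genes by cross order for total expression, for the T homoeolog, for the A homoeolog and for the ratio (969, 962, 876 and 584 at unadjusted p under 0.05), and the 12-library test called 0, 0, 1 and 0; the A homoeolog called was that of AT1G64360 (log2 1.00, SE 0.108, adjusted p = 0.0461), named after its value was seen. The smallest p-values for the total, all with adjusted p = 0.657 and so not past the threshold, were those of AT1G22180 (log2 1.80), AT1G26380 (1.62), AT1G19540 (1.74), WR3 (1.54), AT1G09932 (1.36), ORA47 (-1.92), AT2G27080 (-1.16), COBL8 (-1.11), AT3G13175 (-1.04) and AT2G40010 (-0.77). Within T3A1 the 12-library test called 0 genes between TATT and TTTA (486 at unadjusted p under 0.05, smallest adjusted p = 0.998). Within T1A3 it called 1002 of 13500 genes, 295 higher and 707 lower in TAAA than in AATA. The rises included GolS2 (3.00, SE 0.491), AT1G15125 (2.79), AT4G08780 (2.60), FSD1 (2.58) and the peroxidase gene Prx37 (2.51), and the falls VSP1 (-3.62, SE 0.67), BAM5 (-2.73), AT3G53980 (-2.72), VSP2 (-2.65) and AT3G16670 (-2.34), with adjusted p from 0.0141 to 0.0465. The 1002 calls became 11 without the replicate block, 0 without replicate 1, 3498 without replicate 2 and 0 without replicate 3; the difference between the classes in this effect was tested gene by gene and passed for FAH1 and AAP4 in total expression, but for 0 genes without the replicate block (smallest adjusted p = 0.103).

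Natural A. suecica and AlloF8 were set side by side as allotetraploids with equal numbers of T and A genomes. In A. suecica the lipid transfer protein genes LTP4 and LTP3 had 1420 and 967 RPKM, against 6.11 and 4.73 in AlloF8. FSD1 had 306 RPKM against 8.66. In the opposite direction, the blue copper-binding protein gene BCB had 4.91 RPKM in A. suecica against 705 in AlloF8 and the copper/zinc superoxide dismutase gene CSD2 11.4 against 538. The F8 replicates of CSD2 had 103 and 973 RPKM, those of A. suecica 12.1 and 10.7.

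Of 7766 genes with a mean of at least 10 RPKM, 91 were over 4-fold higher and 346 over 4-fold lower in A. suecica, with a median of -0.27 on the log2 scale over the 7766 genes. No test was planned for this comparison. A limma test on the 2 libraries of each, added after the data were seen, called 523 of 12644 genes for the total (154 higher, 369 lower), among them 88 of the 91 and 296 of the 346, and 2467 of 12644 for the ratio (1266 higher, 1201 lower). For the total its errors were pooled over genes, so the spread of a single gene such as CSD2 hardly counted. The largest log2 ratios were those of AT3G15870 (7.99), LTP4 (7.75), LTP3 (7.53), AT2G25510 (5.20), FSD1 (5.07), AT1G19960 (4.83), the glucosinolate gene ESM1 (3.79), the drought-responsive gene RD22 (3.62), the proline synthesis gene P5CS1 (3.62) and NCED4 (3.60). The lowest were those of BCB (-7.03), AT2G43590 (-5.96), CSD2 (-5.50), AT4G21870 (-5.22), AT3G15356 (-4.99), AT3G15450 (-4.94), AT3G15630 (-4.77), AT5G62360 (-4.72), AT5G44020 (-4.68) and AT5G05600 (-4.65). The total of AT2G43590 was 2110 and 203 RPKM in the AlloF8 libraries and 19.8 and 16.4 in those of A. suecica. The T to A ratio was over 4-fold higher in A. suecica for 112 genes and over 4-fold lower for 184. PRB1 had a T share of 45.9% in A. suecica and 1.17% in AlloF8, and CYP81D1 71.4% and 7.17%, while AT2G33830 had 24.4% and 98.0%, and the chloroplast RNA-binding gene CSP41A 9.93% and 84.0%. The total of PRB1 was 1650 and 64.6 RPKM in the AlloF8 libraries, so its share there rests mainly on replicate 1. The counts were 174 and 209 higher with only replicate 2 or replicate 1 of AlloF8, and 548 lower with only replicate 2 of A. suecica. The log2 difference between replicates had an SD over genes of 1.03 in AlloF8 and 0.364 in A. suecica, so part of the 4-fold differences lay within the spread of the AlloF8 libraries.

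The last comparison asked whether AlloF8, with as many T as A genomes, lay between the F1 classes. The AlloF8 value lay between the class means for 93.3% of T homoeologs (12168 of 13043), 88.4% of A homoeologs (11555 of 13067) and 98.3% of ratios (12773 of 12997). For TOC1, the T share was 65.3% ± 0.696 in T3A1 and 20.0% ± 0.713 in T1A3, and for GI 68.5% ± 0.155 and 13.4% ± 0.036 (SD, n = 2 crosses each). For total expression the share of genes with AlloF8 in between was 49.2% (6453 of 13113), and it was 29.1% and 23.5% with a single AlloF8 library.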

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

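The 12-library test itself was chosen only after the replicate columns were seen, and so were the tests of library rescaling for the dosage classes, of the replicate 2 shift and of a defence state.

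In TAAA replicate 2 the 100 most expressed genes took 24% of summed RPKM, apart from the other T1A3 libraries (29.9% to 32.0%) by Dixon's criterion; chance marks about 1 in 20 groups, and 12 tests were made, on 6 measures in each of 2 groups. For FAH1, a hydroxylase gene of lignin synthesis, the effect of cross order differed between the classes by 1.92 on the log2 scale (SE 0.188, adjusted p = 0.028): TATT minus TTTA was -0.18 and TAAA minus AATA was 1.74. The A homoeolog of FAH1 differed by 2.04 (SE 0.215, adjusted p = 0.0362), and the total of the amino acid permease gene AAP4 by 1.79 (SE 0.202, adjusted p = 0.0474). For the homoeolog ratio the same test passed for FSD1 (-1.53), ATCG00480 (8.17) and ATCG00680 (4.32), each with adjusted p = 0.0467; the latter 2 are plastid genes. ATCG00680 had values in 9 of the 12 libraries, so that its plain means differ from the estimate with the replicate block: TATT minus TTTA was -0.02 and TAAA minus AATA was 3.54. Without the replicate block 0 of these interactions passed (smallest adjusted p = 0.103 for the total, 0.111 for the A homoeolog and 0.107 for the ratio). Genes listed in one class alone took no part in the tests: 21 genes had values in all 6 libraries of T3A1 and in none of T1A3, and 75 had values in all 6 libraries of T1A3 and in none of T3A1. Totals under 2 RPKM are listed as 0, so a gene missing from a class may be expressed there below that limit. Some lay close to it where they were listed, such as FRI with 2.72 RPKM in T1A3. Among the 75 were AT2G44240 with 57.9 ± 60.8 RPKM, AT1G09400 with 27.1 ± 16.2, the ubiquitin gene UBQ12 with 14.7 ± 6.90 and the wall-associated kinase gene WAKL4 with 9.40 ± 4.66 (SD, n = 6 libraries).

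Total expression differed between the dosage classes in 5181 genes over the 12 libraries. The libraries were also split in 100 ways within each replicate number, in a fit on group and replicate number without a mean for each cross. In that fit the real split called 4161 genes. Of the 100 splits 1, the real one, gave as many genes (highest other 883), so chance can be excluded among single libraries but not between crosses, of which 4 make only 3 splits. Rescaling every library to 1 median kept 88% of the called genes (5237 called) and leaving out the 100 most expressed genes kept 96.2% (5105 called), which argues against library scaling and against a few abundant genes as the whole source. If homoeologs of unequal strength were only counted by genome copy, the AlloF8 values would give the direction of each change, and 74.4% of 5056 called genes changed that way (r = 0.461 across all genes, which are not independent replicates). That share lay between the bounds set for and against this explanation, so it cannot be told apart from a response of single genes to dosage. Across genes the change from T1A3 to T3A1 correlated negatively with the replicate 2 shift of TTTA and TATT (r = -0.34). The T1A3 crosses thus leaned toward the state of the replicate 2 libraries. A state of the leaves that varies between libraries may be part of the difference and cannot be told apart from the class. A difference by genome dosage, or by the species crossed to AlloF8, stays open and untested, as each class holds 2 crosses.

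For the homoeologs the same 100 splits excluded chance among single libraries, and not between the 4 crosses, with 1 split as large in each case: 12909 genes for the T homoeolog (highest other 7734), 12978 for the A homoeolog (highest other 5910) and 13323 for the ratio (highest other 10700).

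TAAA differed from AATA in 1002 genes while TATT against TTTA had 0 calls. The 6 libraries allow 4 splits with replicate number kept, too few for a share under 0.05; 1, the real one, gave 1751 genes and the highest other 0. After rescaling 96.3% of the genes were still called (1196 called), which argues against library scaling. Across genes the difference correlated with the shift that replicate 2 shows in TTTA and TATT (r = 0.49; 76.5% of 994 called genes in that direction), so a state of the leaves that varies between libraries may be part of it and cannot be told apart from the cross, and the count was 0 without replicate 1, 3498 without replicate 2 and 0 without replicate 3. An effect of the direction of the cross stays open and untested, as each direction has 1 cross in the class.

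Libraries with the same replicate number deviated together from the means of their crosses: all 18 same-number pairs had a correlation above 0.1 across 12193 genes (0.147 to 0.69), against -0.639 to 0.526 for 36 pairs with different numbers. Between replicate 2 and the others 34.1% of 13516 genes were called, and 92.4% of these were kept after rescaling, which argues against library scaling. Another time of day at harvest stays open, because 50% of the clock genes (6 of 12) were called. In replicate 2 the salicylate and defence list was higher by a median of 1.78 (13 genes higher and 0 lower, camera adjusted p = 3.12e-06, and 0.397 with an estimated correlation), with PR1 higher by 3.19, while nuclear photosynthesis was lower by a median of -0.75 (30 genes lower and 0 higher). A defence state of the leaves used for replicate 2 is therefore a candidate explanation, found and tested on the same data. The labels name no such group, and no biological explanation from the design was tested. Replicate 1 also stood apart: AT3G41768 had 352 to 1000 RPKM there and 5840 to 10600 in replicates 2 and 3 of the crosses. Plastid genes of at least 5 RPKM numbered 0 to 9 and 6 to 29. Only replicate 2 was tested against the others, so differences that do not come from the leaves stay open.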

How the results depend on the processing

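The 12-library test and its settings, other choices of transcript, pairs at 0 taken as 0, values in all 12 libraries, single replicates left out and the share without organelle genes were chosen only after the data were seen; the other settings were set before. Of the values of named genes under an alternative, 1566 kept their direction and side of the threshold or, without a test, their value. Of the others, 161 no longer passed the threshold, 69 now passed it, 140 without a test changed by any amount and 0 reversed. Of counts and shares, 148 stayed within their limits and 68 moved. With cross order as a block the calls were 13087 (T), 12710 (A) and 13360 (ratio), with 0 for the total. At a minimum of 5 RPKM they were 7548, 7621 and 7071, because fewer genes were tested. For the total, 0 in the planned test, the count was 5181 in the 12-library test, 760 for the slope with AlloF8, 138 after rescaling, 17 with pairs at 0 taken as 0, 185 with values in all 12 libraries, and 2 to 3891 with 1 cross left out, where the lone cross of a class is assumed to vary like the others. The 5181 calls became 2907 without the block and 1448 to 6189 with a cross or a replicate left out. The 1002 calls between TAAA and AATA became 11 without the block and 0 to 3498 with a replicate left out, and cross order had 1 call for the A homoeolog in the 12-library test. Departures from the dosage ratio (219 T, 82 A) moved: 4586 and 4901 in the 12-library test, 14 and 125 with pseudocount 0.1, 3998 and 1527 with pseudocount 1, 6 and 9 at 5 RPKM, 89 and 269 after rescaling, 58 and 45 with pairs at 0 taken as 0; for T 41 without the trend and 68 with summed transcripts; for A 20 with robust eBayes, 22 with the first transcript and 145 with values in all 12 libraries. The T share in T3A1 (72.2%) was 75.2% as a median over genes, 71.3% without the 100 most expressed genes, 72.8% with both homoeologs detected throughout and 72.7% without organelle genes; the medians were 23.3% in T1A3 and 49.8% in A. suecica. With 1 library of AlloF8 or A. suecica left out, 65 to 209 genes were over 4-fold higher and 304 to 548 lower in A. suecica, and AlloF8 lay between the classes for 80.7% to 81.5% (T), 73.7% to 79.0% (A), 23.5% to 29.1% (total) and 97.3% to 97.6% (ratio) of genes; this share for T was 94.1% after rescaling and 94.4% at 5 RPKM, and for the ratio 98.5% at 5 RPKM. Of the lists called by camera (11 T, 5 A, 4 total, 5 ratio), 0 were called in each with an estimated correlation, and the 12-library camera called 2 for A. The fry test called 18, 19, 0 and 21. It sets a list against no change and camera sets it against the other genes, so these counts answer another question. The cause was not tested. Read depth is unknown and totals under 2 RPKM are listed as 0, which limits genes of low expression.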

Other observations

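The 12-library test, the plastid and mitochondrial tests and the copper values with 1 library left out were chosen only after the data or the result were seen.

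The 12-library test also read departures from the dosage ratio in abundant genes. On simulated data it called 423 (T) and 667 (A) genes that followed the ratio, so single calls are uncertain. The T homoeologs of the glutathione transferase genes GSTF6 (log2 0.19) and GSTF7 (0.18), the calmodulin gene CAM2 (-0.16), AOC3, an enzyme gene of jasmonate synthesis (0.17), and the cell wall gene EXT3 (-0.03) differed by little between the classes and passed the test against the dosage ratio (adjusted p from 0.000393 to 0.0253). Among A homoeologs this held for ELP (-0.21), AT2G45180 (0.18), the gibberellin-regulated gene GASA1 (-0.11) and the germin gene GER3 (0.21), with adjusted p from 0.000341 to 0.00841.

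Replicate 2 of the crosses differed from the other replicates in several abundant genes. The totals of PR1 (log2 3.19, SE 0.624), PRB1 (3.03), the camalexin gene CYP71A13 (3.09), the transcription factor gene NAC061 (3.10), AT2G30766 (3.33) and SAG21 (2.82) were higher, and those of the ferritin gene FER1 (-3.22, SE 0.366), the light-harvesting gene LHCB2.3 (-3.19), VSP1 (-3.02), COR15A (-2.88), VSP2 (-2.78) and AT3G28220 (-3.79) were lower (limma adjusted p from 0.000101 to 0.00406).

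FSD1 was higher and CSD2 and BCB were lower in A. suecica than in AlloF8, and all 3 belong to a list of copper-responsive genes written before the others were read. All of the 4 other measured members (100%) changed in the listed direction, CSD1 by -3.69, the copper chaperone gene CCS by -2.49, the copper transporter gene COPT1 by 0.12 and the copper chaperone gene CCH by 1.64 on the log2 scale. COPT1 lay within the spread of its replicates (67.4 and 47.2 RPKM in AlloF8, 76.6 and 48.2 in A. suecica), and CCS also differed between the AlloF8 libraries (5.98 and 30.4 RPKM, against 2.67 and 2.98 in A. suecica). The signed median of the 4 genes (2.07) stood at percentile 100 (rounded) among 10000 random lists of like expression. These lists were drawn gene by gene, so the percentile does not allow for copper genes that change together. The signed median was 1.08 without AlloF8 replicate 2 (percentile 97.2, 3 of 4 genes in the listed direction, CCS -0.96 and COPT1 -0.11), 1.84 without A. suecica replicate 1 (3 of 4) and 2.75 and 2.25 without the others (4 of 4). This is consistent with a response to low copper in the A. suecica plants, as a hypothesis; growth conditions and line cannot be separated with 2 libraries of each. FSD1 and CCH were also higher in TAAA than in AATA (log2 2.58, adjusted p = 0.0384, and 1.00, adjusted p = 0.0209), while CSD2 (-0.66, adjusted p = 0.134), BCB (0.72, adjusted p = 0.151), CSD1 (-0.03, adjusted p = 0.957), CCS (0.04, adjusted p = 0.936) and COPT1 (0.24, adjusted p = 0.456) did not pass, and BCB and CCS changed against the listed direction.

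Plastid genes had opposite homoeolog shares in the T1A3 crosses: the median T share over plastid genes of at least 5 RPKM was 8.33%, 3.84% and 3.36% in the AATA libraries, against 23.0% to 23.9% for nuclear genes, and 59.1% (6 genes, 3.07% to 92.8%) and 61.6% in TAAA replicates 2 and 3, while TAAA replicate 1 had 0 such genes. It was 66.9% and 65.0% in AlloF8, 66.3% and 66.1% in A. suecica and 77.9% to 83.9% in the T3A1 libraries with at least 9 such genes. Plastids inherited from a mother named first would give opposite shares, but these shares prompted the idea and so cannot support it. Mitochondria would follow the same mother: of the libraries of AATA and TAAA, 4 had at least 3 mitochondrial genes of at least 5 RPKM, with a median T share of 8.61% and 5.20% in AATA and of 15.4% and 30.9% in TAAA, where only the last lay above the nuclear share. The mitochondrial share also lay below the nuclear share in AlloF8 (35.1% and 34.2%), in A. suecica (33.7% and 17.1%) and in each T3A1 library with a value. The nuclear share is thus no neutral reference for mitochondrial genes, and this test cannot decide. Inheritance of organelles from a mother named first stays open. Plastid genes are transcribed and inherited together and are not independent, and the way in which reads of organelle genes were assigned to a homoeolog is not given in the sources used here.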
